A study of Zea mays with 6 samples.

How the data were processed

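Polyadenylated RNA of maize (Zea mays) seedlings at the coleoptile stage was sequenced from 3 wild-type and 3 Fdl1-/- samples, with 3 biological replicates per group as the series design states. Per the labels' protocols, RNA was extracted with a PureLink kit and libraries were made with a stranded TruSeq mRNA kit. Bowtie2, RSEM, DESeq2 and limma are named in the submitters' processing notes, without versions or roles, together with the maize genome build B73 RefGen_v4. Per the file headers, each deposited table is RSEM gene output with the expected count, TPM, FPKM, length and effective length of 45855 genes. The deposited expected counts are estimates that divide reads shared between genes, and the deposited TPM values are scaled to transcript length and library total. The deposited FPKM values were not used here. The effective length equalled the length less 49 nt for 100% of gene values, which is what reads of 50 nt would give.

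Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total count of 15, libraries were scaled by TMM, and the quasi-likelihood test was two-sided with Benjamini-Hochberg adjustment at 0.05. All 6 libraries entered the fit, with no replicate block. CPM values, counts scaled to a common library size, are on the TMM scale, and log-CPM used a prior count of 2. Standard errors of log2 fold changes were taken from the fold change and the F statistic. Library totals ran from 26807205 to 36123679 expected counts. A floor of 3 counts corresponded to 0.084 to 0.114 CPM per library. Intervals of ratios and floors cover counting error only.

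The edgeR fit was tested on simulated counts for 26098 genes, of which 200 were changed. The first criterion asked that at least 80 of 100 genes changed 4-fold be recovered, and 68 were, so it was not met. It was replaced, after that result was seen, by a criterion on the median log2 estimates, so 2 versions of the check were used and the second was not set in advance. The median estimates were 0.98 for 2-fold and 1.97 for 4-fold changes. Of 100 genes changed 2-fold, 29 were recovered. All recovered genes had the right sign, and 7 unchanged genes were called. Genes with changes of these sizes are therefore missed in part at this depth and replicate number.

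The files name genes by ID. A table of gene symbols for assembly NAM-5.0 matched 153 of 154 microRNA IDs, 0 of 43789 IDs beginning Zm00001d, 0 of 174 beginning GRMZM5G and 0 of 1738 beginning ENSRNA. The 31 gene lists fixed before the data were examined therefore had 0 members, and their tests were not run. The ID of FDL1, Zm00001d022227, was recalled from published work that was not at hand, and no table used here pairs it with the name. Every result on the FDL1 locus and its neighbours rests on that ID. Other genes were named by a rule fixed before the data were examined. It takes the largest fold changes each way among genes with adjusted p under 0.05, with groups that do not overlap and a mean of at least 1 CPM in the higher group. Without descriptions the rule allows at most 2 IDs each way. Gene numbers are the numbers in the gene ID column of the deposited tables, and gene IDs were taken from the transcript IDs. Of 152 neighbouring pairs of named microRNA genes, 142 lay on one chromosome, and all 142 were in ascending order.

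Alternatives were other scalings, DESeq2 1.42.0, limma 3.58.1 on counts and on TPM with pseudocounts of 1 and 0.1, other filters and thresholds, effective lengths as offsets, a replicate block, and leaving out each library in turn. Removal of the transcript length trend and windows in gene numbers were chosen after the data were seen. Windows in megabases were not run, since coordinates of the build were not used here.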

Results

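Gene expression was measured by RNA sequencing in whole maize seedlings at the coleoptile stage, in 3 wild-type and 3 Fdl1-/- samples. FDL1 (fused leaves1) encodes a MYB transcription factor known for its part in cuticle deposition and organ separation in young maize seedlings. Each library held 26807205 to 36123679 expected counts, and 31480 to 32380 of the 45855 genes had a count in a library. The 20 most abundant genes took 6.51% to 6.96% of the counts of a library. Pearson correlations of log-CPM across genes were 0.973 to 0.980 between mutant libraries, 0.938 to 0.975 between wild-type libraries and 0.918 to 0.962 between the groups. Wild-type replicate 1 lay apart, with a mean correlation of 0.944 with the other wild-type libraries.

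**Figure D1:**
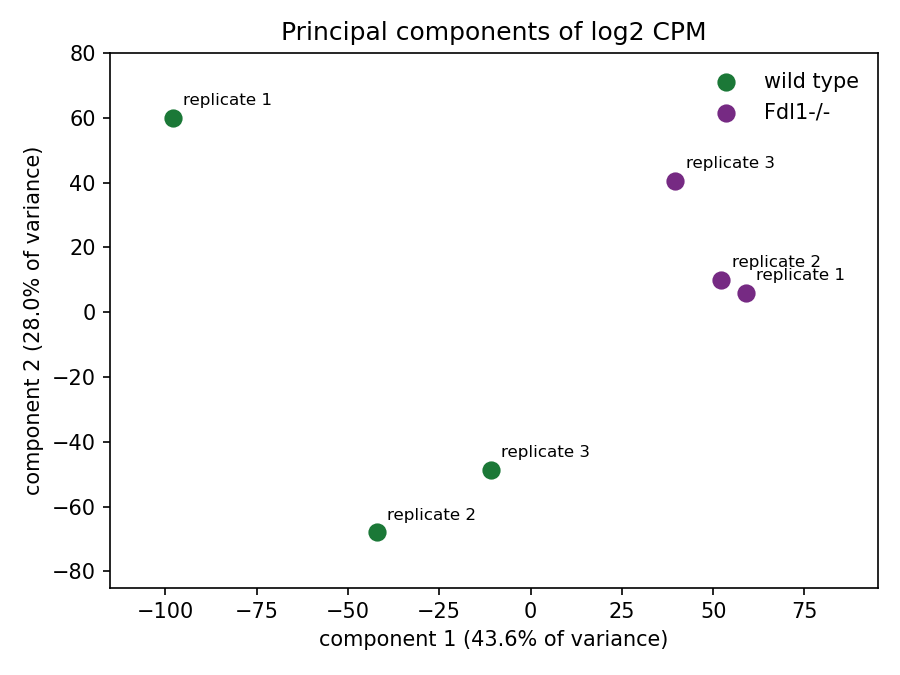
Principal components of log2 CPM for the 6 libraries, with component 1 (43.6% of the variance) on the x axis and component 2 (28.0%) on the y axis; each point is a library, coloured by genotype. The 3 mutant libraries lie at 39.7 to 59.0 on component 1, and the wild-type libraries lie at -97.9, -42.1 and -10.9.

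The FDL1 locus was still transcribed in the mutant seedlings, and its expression did not pass the test for a difference from wild type. Its expression was 4.82 ± 0.816 CPM in wild type and 3.95 ± 0.376 CPM in Fdl1-/- (SD, n = 3). Its estimated mean transcript length was lower in every mutant library, at 1613 ± 7.47 nt in wild type and 1546 ± 6.87 nt in Fdl1-/- (SD, n = 3). This is the length given by RSEM, which weights annotated transcripts by their estimated shares. A shift in it does not show that any transcript was itself shorter. The locus, Zm00001d022227, has 2 annotated transcripts, and its ID was recalled from published work and not paired with the name by a table used here. This comparison checks the genotype labels. Wild-type replicates 1, 2 and 3 had 5.18, 3.88 and 5.39 CPM, from 136, 137 and 179 expected counts. Mutant replicates 1, 2 and 3 had 4.39, 3.75 and 3.72 CPM. The log2 fold change was -0.28 (SE 0.23, 95% interval -0.82 to 0.25), with an adjusted p of 0.651 in edgeR's quasi-likelihood test. The difference in length gave a two-sided exact permutation p of 0.1, the smallest that 3 against 3 samples allow. It did not pass a test of transcript length across 11778 genes (limma, adjusted p 0.377). The labels used here do not give the lesion of the allele, so the expression level alone does not separate the genotypes.

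**Figure D2:**
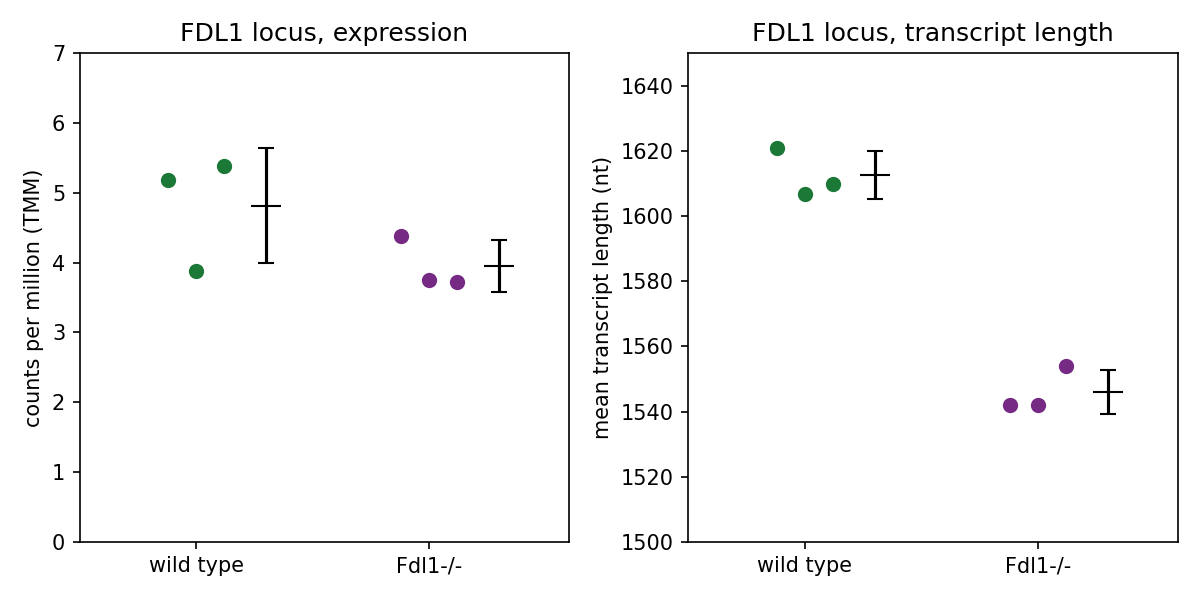
Expression of the FDL1 locus in CPM (left) and its mean transcript length in nt (right, on an axis that does not start at 0) in wild-type and Fdl1-/- libraries; points are libraries and bars are the mean and SD of 3. Expression overlaps between the genotypes, and transcript length does not (1606.83 to 1621 nt against 1542 to 1553.9 nt).

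Among genes with an adjusted p under 0.05, more rose than fell in the mutant seedlings. Over all tested genes the median log2 fold change was -0.033, so tested genes in general did not shift upward. The excess is stated for genes past this threshold, and directions just short of it were not counted. Of 26098 genes tested, 439 were higher and 260 were lower in Fdl1-/-, so 62.8% of the 699 changed genes rose. The genes that rose also moved further, with a median log2 fold change of 1.95 against -1.04 for the genes that fell. This median is also 1.95 when the 7 genes with no count in any wild-type library are set to their bounds. Together the higher genes took 0.774% ± 0.083 of the counts in wild type and 2.48% ± 0.308 in the mutant (SD, n = 3). The lower genes took 1.69% ± 0.110 and 0.834% ± 0.0511 (SD, n = 3). Both sets were chosen for their change, so these shares describe its size only. With those bounds 370 genes rose at least 2-fold and 121 at least 8-fold, while 137 and 10 genes fell that far. The excess of higher genes lay mostly at low abundance, with 39 higher and 7 lower under 1 CPM and 152 and 42 between 1 and 10 CPM. Between 10 and 100 CPM 216 were higher and 183 lower, and above 100 CPM 32 and 28. The median size of the log2 change of changed genes was 2.31 between 1 and 10 CPM, 1.10 between 10 and 100 CPM and 1.04 above, and it was larger still under 1 CPM. The libraries of the groups did not overlap for any of the 699 genes. Among all tested genes 21.9% did not overlap, where chance gives 10%. The comparison asks which genes differ between seedlings labelled Fdl1-/- and wild type, and calls rest on edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05. DESeq2 called 1993 genes, 1089 higher and 904 lower, so 54.6% were higher. Without wild-type replicate 2, or mutant replicates 1, 2 or 3, the count was 149, 128, 184 or 193. Of these 33, 19, 32 or 47 were lower, and 77.9%, 85.2%, 82.6% or 75.6% were higher.

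**Figure D3:**
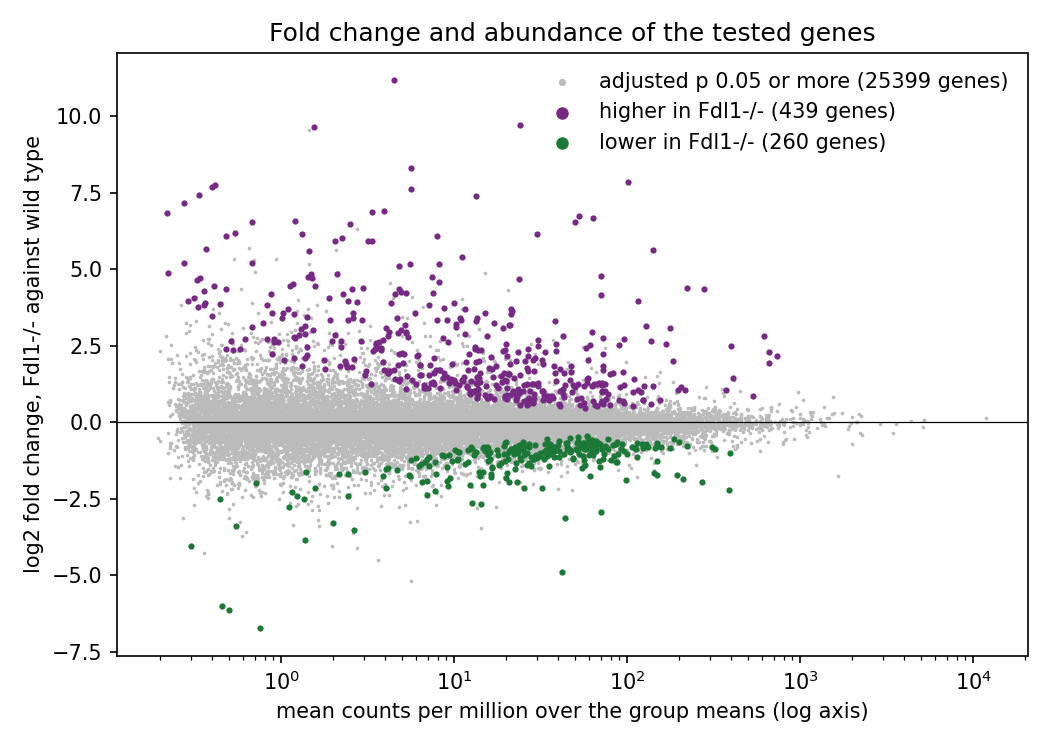
Log2 fold change of Fdl1-/- against wild type (y axis) and mean CPM (x axis, log scale) of the 26098 tested genes; each point is a gene, coloured where the adjusted p of edgeR is under 0.05. The 439 higher genes reach larger changes than the 260 lower genes.

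Several genes had few or no counts in one genotype and clear counts in the other. Counts are reads assigned to annotated genes, so few counts alone do not show that a gene was silent. Whether the sequence of these genes differed between the groups was not tested. Zm00001d032984 had 0 counts in every wild-type library and 254 to 325 counts in the mutant libraries. At 8.93 ± 0.145 CPM (SD, n = 3) it was at least 92.5-fold higher than a floor of 3 counts per library, with an adjusted p of 0.00221 in edgeR. Zm00001d028561 had 1 to 3 counts in wild type and 968 to 2584 in the mutant, where it reached 47.6 ± 24.3 CPM (SD, n = 3). Its ratio was 913 (95% counting interval 391 to 2814), with an adjusted p of 0.00136 in edgeR. Its fitted log2 fold change was 9.72, and 10.36 without wild-type replicate 3. Zm00001d022147 fell from 1.50 ± 0.182 CPM (SD, n = 3) in wild type to 1 count over the 3 mutant libraries, and it lies 76 gene numbers from FDL1. The wild-type level was 148 times the mutant level (95% counting interval 26.1 to 5874), with an adjusted p of 0.00943 in edgeR. The 1 count lay in mutant replicate 1, and without that library the gene was at least 17.4-fold lower in the mutant, against a floor of 3 counts per library. Zm00001d011183 was lower in the mutant but not near 0 counts, with 51 to 164 counts in the mutant libraries. It fell from 80.7 ± 67.0 CPM in wild type to 2.71 ± 1.63 CPM in the mutant (SD, n = 3). The fitted log2 fold change of this gene was -4.88 (SE 0.72), with an adjusted p of 0.0226 in edgeR. Its log2 fold change was -3.95 without wild-type replicate 1 and -5.51 without mutant replicate 2. The adjusted p of Zm00001d011183 was 0.0589 in limma-voom and 0.0581 to 0.107 without wild-type replicate 2 or any 1 of the mutant replicates. For each of these 4 genes the expected counts were whole, within 0.005, in 0 of the 3 libraries of the group with the higher level. Their values are uncertain where reads were divided between similar genes. In all, 34 higher genes had at most 3 counts in every wild-type library, and 4 lower genes had at most 3 in every mutant library. Many of them were low in both groups. The 4 lower genes had a median of 0.943 CPM in wild type, and the 34 higher genes one of 0.829 CPM in the mutant. DESeq2 gave 79 such higher genes, and 10, 10, 14 and 11 were left without mutant replicates 1, 2 and 3 and wild-type replicate 2. A replicate block left 7. A filter of 1 CPM in 3 libraries, which drops genes this low by its own rule, left 12. With limma on TPM there were 16 and 17, for pseudocounts of 1 and 0.1.

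Among 6 tested microRNA genes, measured through their polyadenylated primary transcripts, 0 passed the threshold in edgeR, with 0 at an unadjusted p under 0.05. DESeq2 and limma-voom also called 0. MIR159a, of a family known to target MYB transcripts, had 3.24 ± 0.667 CPM in wild type and 3.10 ± 0.365 CPM in Fdl1-/- (SD, n = 3). Its log2 fold change was -0.066 (SE 0.26, 95% interval -0.69 to 0.55), with an adjusted p of 0.945 in edgeR. Its sign turned without wild-type replicates 2 or 3 or mutant replicate 1, where it was 0.0021, 0.047 and 0.034. Adjusted p values in edgeR were 0.715 to 0.997 for the other 5 microRNA genes tested, MIR169c, MIR408b, MIR396a, MIR156f and MIR159f. Of 122 tested IDs beginning ENSRNA, 1 rose and 0 fell, and 0 passed in edgeR when adjusted over the list alone, with 8 at an unadjusted p under 0.05. DESeq2 called 2 and limma-voom 1 of this class. Of 80 tested IDs beginning GRMZM5G, 1 rose and 0 fell, and 0 passed when adjusted over the list alone, with 5 at an unadjusted p under 0.05. DESeq2 called 2 and limma-voom 1 here too. ENSRNA genes took 2.11% ± 0.181 of counts in wild type and 2.08% ± 0.175 in Fdl1-/- (SD, n = 3, exact permutation p = 1).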

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

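The transcript length test and its use around FDL1 were chosen after the data were seen. The deposited tables hold an estimated mean transcript length per gene, which the comparison of expression does not use. Zm00001d021993 passed the test on that measure, with a log2 difference of -0.33 in mean transcript length between Fdl1-/- and wild type (limma, adjusted p 0.0347). Its mean length was 1782 ± 25.7 nt in wild type and 1415 ± 10.1 nt in the mutant (SD, n = 3), over 5 annotated transcripts. It was the 1 gene of 11778 tested that passed, and 578 had an unadjusted p under 0.05. Its expression log2 fold change was -0.70 (SE 0.14), with an adjusted p of 0.0539 in edgeR. The gene lies 220 gene numbers from FDL1. Of the 10 splits of the 6 libraries, 3 gave as many genes, the real one included, with 1 as the highest of the others. With 10 splits a share under 0.05 cannot be reached.

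Wild-type replicate 1 lay apart, with a mean correlation of 0.944 with the other wild-type libraries, where other pairs within a group lay at 0.973 to 0.980. Its deviation from them followed transcript length, with a Spearman correlation across genes of -0.37. Removing each library's length trend raised the mean correlation to 0.948 only, and thinning every library to the smallest total left the lowest other pair at 0.973. These values argue against transcript length as the whole difference and against depth. A part of the difference tied to transcript length is not excluded. A difference between the seedlings sampled also stays open and was not tested.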

How the results depend on the processing

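Removal of the length trend, the windows in gene numbers and leaving out genes near FDL1 were chosen after the data were seen. With the length trend removed 878 genes changed, 525 higher and 353 lower, so 59.8% were higher. The odds ratio near FDL1 was then 3.78. DESeq2's Wald test called 1993 genes (1089 higher, 904 lower), including all 699 of edgeR. An adjusted p under 0.01 left 121 (98 and 23), and a 2-fold minimum left 137 lower genes. Same-numbered samples had correlations of deviations of -0.22, 0.13 and -0.18, where other pairs of a wild-type and a mutant sample ran from -0.18 to 0.27. These values gave no sign of pairing by number. They cannot exclude it, since deviations from a mean of 3 samples constrain each other. A replicate block left 122 genes (105 and 17), and the odds ratio near FDL1 was then 2.48 (Fisher's exact p 0.127). Under it Zm00001d032984, Zm00001d022147 and Zm00001d011183 had adjusted p of 0.0624, 0.0727 and 0.0814. The block leaves fewer residual degrees of freedom. Leaving out 1 library gave 128 to 837 genes, 109 to 528 higher and 19 to 309 lower, with 149, 128, 184 and 193 genes without wild-type replicate 2 and mutant replicates 1, 2 and 3. The causes were not tested. No gene called in edgeR changed sign in any of these fits. The libraries of the groups did not overlap for any of the 699, so this was largely fixed in advance and tells little of stability. The log2 fold change of MIR159a ran from -0.23 to 0.047 when 1 library was left out. Among 3 other scalings the lowest share of higher genes was 63.9%. These scalings differed little from TMM, with median log2 fold changes of all tested genes of -0.030 to -0.011 against -0.033. They could hardly move the share, so a larger error of scaling was not tested. The log2 fold change of the FDL1 locus was -0.42 to -0.14 and passed the threshold under none of the alternatives run. Alternatives of the gene lists and windows in megabases were not run. In simulated data 29 of 100 2-fold changes were recovered, which limits what this design detects.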

Other observations

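The circular shifts, the direction tests, the length tests near FDL1, the comparison of whole counts with all tested genes, the windows and the random placement of neighbouring pairs were chosen after the pattern was seen. Genes near FDL1 in the gene order changed more often than genes elsewhere. Within 200 gene numbers of the locus 29 of 264 tested genes changed, 10 higher and 19 lower. Elsewhere 2.59% of tested genes changed (odds ratio 4.63, 95% interval 3.01 to 6.89, two-sided Fisher's exact p 1.5e-10). Zm00001d022147, with 1 count over the mutant libraries, is among them. Within 100 gene numbers the share was 13.8%, and within 1000 it was 5.05%. Chromosome ends were not placed in the gene order, so a window, the widest above all, may hold genes of another chromosome. The odds ratio was 2.70 with the calls of DESeq2, 2.48 with a replicate block (Fisher's exact p 0.127) and 3.17 to 4.99 when 1 library was left out. The 29 changed genes became 7, 4, 7 and 6 without wild-type replicate 2 and mutant replicates 1, 2 and 3, and 3 with the block. Without mutant replicate 1 the Fisher's exact p was 0.0413.

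Chance placement would have to give as many calls in a window, and 0.207% of circular shifts did, all of them overlapping the window itself. Shifted windows that did not overlap it held up to 18 changed genes, against a median of 7 over all shifts. Changed genes thus also lay close together away from FDL1. Zm00001d028554, Zm00001d028555, Zm00001d028557 and Zm00001d028561, at gene numbers 1210, 1211, 1214 and 1217, all rose. The last of these lies 29441 gene numbers from FDL1. Draws of genes matched on abundance held at most 17 changed genes, which argues against abundance. Linked sequence carried with the mutant allele is a candidate explanation. In the window 65.5% of changed genes fell, against 241 of 670 elsewhere (Fisher's exact p 0.00255). Over all 264 tested genes of the window, changed or not, 57.6% had a log2 fold change below 0, against 54.8% elsewhere (Fisher's exact p 0.385), so a general lowering was not detected. Genes with an unadjusted p under 0.01 for transcript length in limma made up 2.49% of 603 genes within 1000 gene numbers and 1.09% elsewhere (odds ratio 2.31, Fisher's exact p 0.00507). That count leaves out FDL1, and without Zm00001d021993 too the odds ratio was 2.16 (Fisher's exact p 0.0161). Of all 11778 genes 1 passed the adjusted threshold, so most of these are not calls. The window of 1000 gene numbers may also hold genes of another chromosome, so the share in it does not measure linkage alone. Effects of FDL1 itself on its neighbours stay open and were not tested.

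Beyond 1000 gene numbers from FDL1, neighbouring genes also rose or fell together. Among the 635 changed genes there were 21 pairs at most 2 gene numbers apart that changed in one direction, 17 of them higher. Random placement gave 7.26 pairs on average and at most 20 (permutation p 0.0001, the smallest 10000 draws can give). Reads shared between near-identical neighbours may account for part of this. Expected counts were not whole, within 0.005, for 81.6% of the genes in such pairs and 58.8% of other changed genes (odds ratio 3.10, Fisher's exact p 0.00569). Among all other tested genes the share was 68.2% (odds ratio 2.06, Fisher's exact p 0.0827), so this explanation stays open. Joint regulation of neighbours was not tested.

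For the 699 changed genes, 1 of the 10 splits of the 6 libraries, the real one, gave as many, and the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached.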
